A study of Mus musculus with 30 samples.

How the data were processed

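RNA was measured in mouse hearts at 2 months of age, collected at ZT10, that is, 10 hours after lights on in the convention of zeitgeber time. The labels name 6 RNA libraries, 3 labelled control (floxed alleles) and 3 labelled CM-RevDKO, a cardiomyocyte double knockout of the REV-ERB receptors made with Cre under the alpha myosin heavy chain promoter, per the labels' protocols. If the controls lack Cre, an effect of Cre itself cannot be told apart from loss of the receptors in any comparison below. The atria were trimmed before extraction, total RNA was taken with TRIZOL and libraries were made with the NEBNext Ultra II kit, per the labels' protocols. The series holds 30 samples; the other 24, from ChIP, Cut&Run and their controls, were not analysed here.

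The authors deposited a table of 13575 genes with 1 value per gene and library. HISAT2, StringTie and the build mm10 are named in the submitters' processing notes, with no version and no annotation; whether reads were assigned by strand is not given in the sources used here. The deposited values were read as FPKM, mapped fragments scaled to transcript length and library size, which StringTie reports. The header of the table does not name the unit. TPM could not be excluded: the values sum to 678722 to 712158 per library over a table in which every gene reaches a value of 1 in at least 1 library. Within a library FPKM and TPM differ by a single factor. The sums of the libraries differ by at most 0.07 on the log2 scale. All 6 value columns matched the labels by group and replicate number.

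Depth could not be recovered. Where whole reads are counted, ratios of low values between libraries repeat; here, in each of the 15 pairs of libraries, at most 4 of 1405 to 1825 low genes shared a log2 ratio to 4 decimals. Sequencing depth is therefore unknown, and no counting interval or detection floor is given. An entry of 0 in such a table can be a failed estimate, so genes with entries of 0 are given per library. Symbols are those of the deposited table. For 13118 genes the symbol matched the RefSeq annotation of GRCm38.p6, which is mm10, and coordinates come from there, 1-based. Genes that overlap or have close copies, such as Nr1d1 and Thra, the globins, the immunoglobulin segments and ribosomal proteins with their pseudogenes, can share reads, and their values are uncertain for that reason.

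Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes with low values. The 13256 genes with a mean of at least 0.5 over the 6 libraries were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, group as the only term), and two-sided p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Each adjusted p of a single gene in the text comes from this fit. The labels do not say whether replicates are separate animals, so the p-values measure only the spread between these samples. No 2 libraries held identical values. The named-gene rule, the alternative settings, except 3 named as added later, and 53 gene lists were fixed before the data were examined. The lists are pathways, cell type markers and technical groups, with 1128 distinct symbols, of which 1001 were tested. Each list was tested with limma's camera with a preset correlation of 0.01 and adjusted over the 53 lists. Camera with a correlation estimated per list, and fry, were run beside it. Members past the test are counted over all genes tested and also adjusted over the list alone.

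The rule for named genes takes 14 clock, NAD and cardiac genes (Nr1d1, Nr1d2, Nfil3, Nampt, Arntl, Npas2, Clock, Cry1, Dbp, Per2, Nppa, Nppb, Myh6 and Myh7). It adds the 8 largest rises and 8 largest falls past the test, among genes with a mean of at least 1 FPKM in the higher group and no overlap between groups, leaving out provisional symbols. From each list that was called or held at least 3 members past the test it takes up to 3 members with the smallest p, or 2 members, given as not past the test, where no member passed. The rule gave 60 genes, not all of which are reported here. Cd79a, Thra and the transcripts that set single libraries apart lie outside it and were chosen after their values were seen, as were further genes so named in the text.

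The procedure was tested on simulated data for this comparison, with 13256 genes, 200 of them changed, in 10 simulations. It recovered 13.4% of genes changed by 0.5, 78.6% of those changed by 1 and 97.3% of those changed by 2 on the log2 scale, and 6.78% of its calls were false. A list shifted by -0.25 was called in 10 of 10 simulations, and 1 of 490 tests of lists that were not shifted was called. Simulated genes varied independently of each other, with a single spread per gene and no structure shared between libraries. These list rates therefore do not cover lists whose members vary together, and the 6.78% does not cover libraries that stand apart. In the data, the correlation estimated within the called lists ran from -0.06 for NAD synthesis to 0.77 for red blood cell markers. Alternatives were the replicate number as a block, each library left out in turn, a pseudocount of 0.1, no filter on low values, a mean of at least 5, median-of-ratios scaling, quantile normalization, scaling without mitochondrially encoded genes, array weights, and a test against a fold change of 1.5. A further 3 alternatives were added after seeing the data; in that with a single CM-RevDKO library, the spread comes from the 3 controls and the lone library is assumed to vary like them. Figures were drawn with matplotlib 3.10.9.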

Results

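The series addresses what the REV-ERB nuclear receptors, transcriptional repressors of the circadian clock, do in the heart. RNA was sequenced in 6 heart libraries, 3 labelled control and 3 labelled CM-RevDKO, the label of a cardiomyocyte double knockout of both receptors, at 2 months of age and ZT10. The deposited table gives values, read as FPKM, for 13575 genes, of which 13256 were tested. Between 11967 and 12395 genes reached 1 FPKM in a library, and mitochondrially encoded transcripts held 36.9% to 41.0% of the summed values. Sequencing depth is unknown. With RNA from ZT10 alone, a clock gene's changed level cannot be told apart from a changed timing of its rhythm.

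The targeted genes came first, since their level can check the labels. Nr1d1, which encodes REV-ERBα (ENSMUSG00000020889, chromosome 11, 98767932 to 98775377, mm10), stood at 23.9, 22.6 and 15.0 FPKM in the libraries labelled control and at 55.6, 47.4 and 47.9 FPKM in those labelled CM-RevDKO. Its log2 fold change was 1.28 (SE 0.17, adjusted p = 0.0124), against the direction the label gives. Nr1d2, which encodes REV-ERBβ (ENSMUSG00000021775, chromosome 14, 18204056 to 18239106), stood at 40.3, 30.6 and 36.3 FPKM in the libraries labelled control and at 28.8, 26.6 and 26.7 FPKM in those labelled CM-RevDKO, a log2 fold change of -0.36 (SE 0.12) that did not pass the test (adjusted p = 0.175). Gene-level values that include exons outside the deleted part check nothing about the deletion, and the deleted exons are not given in the sources used here. The knockout is labelled as one of cardiomyocytes, and transcripts of other heart cells, which keep both genes by design, enter these values too. The labels were therefore not checked by these genes, and every direction below rests on them. The gene Thra overlaps Nr1d1 from 98767932 to 98769006, and without strand the reads of this stretch cannot be told apart. Thra had means of 31.5 FPKM in the libraries labelled control and 22.5 FPKM in those labelled CM-RevDKO. The call of Nr1d1 held with each library left out in turn and ended against a fold change of 1.5 (adjusted p = 0.407). Of alternatives chosen after seeing the data, it also ended without control replicate 2 and CM-RevDKO replicate 1 (adjusted p = 0.0730). With atrial transcripts as a covariate it ended too (adjusted p = 0.187).

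**Figure D1:**
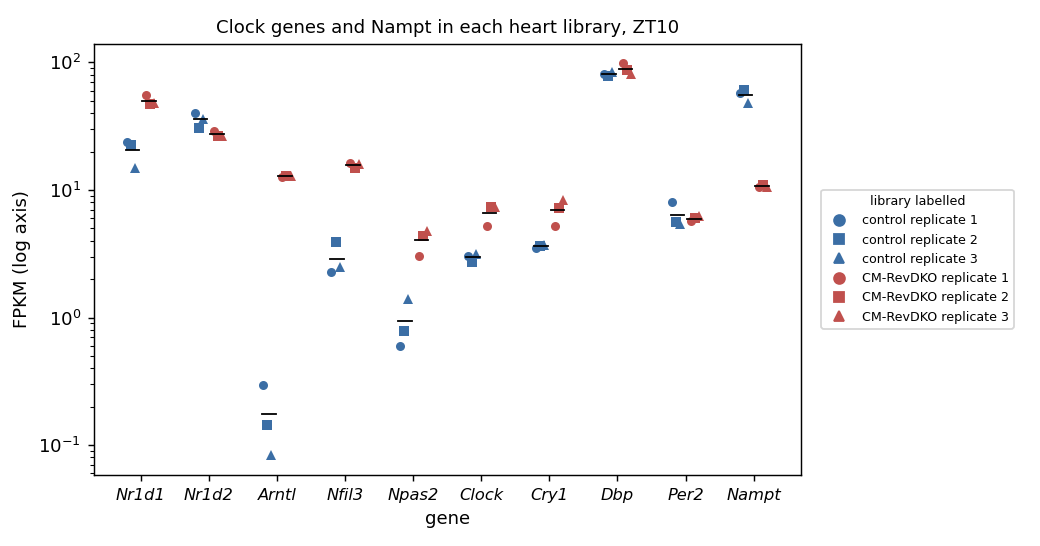
FPKM on a log axis of the targeted genes, other clock genes and Nampt in each of the 6 libraries, with group means as black bars. Arntl stood at 0.0831 to 0.295 FPKM in the libraries labelled control and at 12.5 FPKM or more in those labelled CM-RevDKO, while Nr1d1 was higher and Nampt lower in the latter.

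In the libraries labelled CM-RevDKO, 5 of 8 clock genes with ROR elements rose, Arntl among them, 1 fell and 2 did not pass the test. The NAD synthesis enzyme gene Nampt fell, 3 of 44 genes of fatty acid uptake and beta oxidation fell, and the natriuretic peptide genes Nppa and Nppb rose. Camera with its preset correlation called the clock list higher and the fatty acid list lower, but they had adjusted p = 0.568 and 0.571 with an estimated correlation. By fry the clock list was called (adjusted p = 0.00617) and the fatty acid list was not (adjusted p = 0.0790). In all, 332 genes differed, 167 higher and 165 lower; 84 of the first and 66 of the second differed at least 2-fold in mean FPKM. The values of the groups did not overlap for any of the 332 genes. Such a lack of overlap was seen for 3058 of the 13256 genes (23.1%, where chance gives 10%), and 2206 genes had an unadjusted p under 0.05. Scaled without the mitochondrially encoded genes, 118 genes were higher and 212 lower. The count fell to 120, 149 and 136 without control replicate 1, 2 or 3. It fell to 213 and 121 without CM-RevDKO replicate 1 or 2. Without CM-RevDKO replicate 3 it was 322, of which 208 were shared with the 332. That fit keeps CM-RevDKO replicates 1 and 2, which stood apart from the other libraries in some abundant transcripts. Against a fold change of 1.5 the count was 35. Of alternatives chosen after seeing the data, it was 105 without control replicate 2 and CM-RevDKO replicate 1, and 39 with atrial transcripts as a covariate.

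Of 8 measured clock genes with ROR elements, where REV-ERB competes with the ROR activators, 5 rose and 1 fell in the libraries labelled CM-RevDKO (6 and 1 adjusted over the list alone). Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113178471 to 113314126), rose from 0.174 ± 0.109 to 12.8 ± 0.229 FPKM (SD, n = 3), a log2 fold change of 3.56 (SE 0.11, adjusted p = 1.72e-05). Nfil3, which encodes the repressor E4BP4 (chromosome 13, 52967209 to 52982878), rose from 2.89 ± 0.875 to 15.7 ± 0.823 FPKM (log2 2.13, SE 0.16, adjusted p = 0.00111). Npas2 and Clock, partners of BMAL1, rose from 0.932 to 4.06 FPKM (adjusted p = 0.0168) and from 2.97 to 6.65 FPKM (adjusted p = 0.0186), and Nr1d1 is the fifth member that rose. Cry1 stood at 3.63 and 6.94 FPKM and did not pass the test (adjusted p = 0.0540). As a list these genes had a median log2 fold change of 1.11 (camera adjusted p = 7.23e-05). The adjusted p was 0.568 with an estimated correlation, and fry gave an adjusted p of 0.00617. Npas2 lost its call without control replicate 1 or 2 or CM-RevDKO replicate 2 or 3 (adjusted p up to 0.0779), and Clock with any library but CM-RevDKO replicate 1 left out (adjusted p up to 0.0839), whereas Cry1 passed without CM-RevDKO replicate 1 (adjusted p = 0.0199).

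The clock output genes driven by E-boxes and D-boxes went both ways. Of 15 measured, 2 rose and 1 fell (3 and 4 adjusted over the list alone), with a median log2 fold change of -0.07 (camera adjusted p = 0.722). Gm129, the repressor also called Ciart, rose from 8.11 to 14.0 FPKM (adjusted p = 0.0151). Leo1, a subunit of the Paf1 elongation complex, rose from 2.33 to 5.96 FPKM (adjusted p = 0.0143). Wee1, a kinase that holds back mitosis, fell from 7.93 to 4.17 FPKM (adjusted p = 0.0140). Dbp stood at 81.2 ± 2.90 and 88.8 ± 8.80 FPKM (SD, n = 3, adjusted p = 0.575) and Per2 at 6.38 ± 1.44 and 5.97 ± 0.272 FPKM (SD, n = 3, adjusted p = 0.872). Wee1 and Gm129 lost their calls without control replicate 2 or 3 or CM-RevDKO replicate 2 (adjusted p up to 0.0626 and 0.0682), and Leo1 without control replicate 3 or CM-RevDKO replicate 2 (adjusted p up to 0.0688).

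Nampt, the rate-limiting enzyme of the NAD salvage pathway (ENSMUSG00000020572, chromosome 12, 32820335 to 32853369), fell from 55.9 ± 6.63 to 10.7 ± 0.216 FPKM in the libraries labelled CM-RevDKO (SD, n = 3), a log2 fold change of -2.28 (SE 0.11, adjusted p = 1.40e-04). Naprt1, which makes NAD from nicotinic acid, fell from 6.98 to 3.66 FPKM (adjusted p = 0.0170). These were the 2 members that fell of 10 measured in the NAD synthesis list, and none rose; adjusted over the list alone the counts were again 2 and 0. The list had a median of -0.19 on the log2 scale (camera adjusted p = 0.0125; adjusted p = 0.568 with an estimated correlation; fry adjusted p = 0.00704). Without control replicate 3 the median was -0.10, and with a mean of at least 5 FPKM it was -0.34. Of 21 genes of NAD use and breakdown, none passed the test (camera adjusted p = 0.848). Naprt1 lost its call without any of the 3 control libraries or without CM-RevDKO replicate 2 (adjusted p up to 0.0804).

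Of 44 measured genes of fatty acid uptake and beta oxidation, 3 fell and none rose in the libraries labelled CM-RevDKO, 9 fell adjusted over the list alone, and 36 had a negative log2 fold change. The list was called lower by camera (median -0.24, adjusted p = 4.15e-06; adjusted p = 0.571 with an estimated correlation) and not by fry (adjusted p = 0.0790). Slc22a5, the carnitine transporter, fell from 9.56 to 5.14 FPKM (adjusted p = 0.0236), and Cd36, the fatty acid translocase, from 379 to 269 FPKM (adjusted p = 0.0471). Cd36 was also the single call among 23 PPARα target genes, of which 6 fell adjusted over the list alone; their median was -0.34 (camera adjusted p = 8.05e-05; adjusted p = 0.717 with an estimated correlation; fry adjusted p = 0.231). Of 23 genes of lipid storage and lipolysis, 4 fell and none rose (6 lower and 3 higher adjusted over the list alone), but the list was not called (median -0.13, camera adjusted p = 0.131). Enzymes of triglyceride assembly were among them: Gpam fell from 50.3 to 24.6 FPKM, Dgat2 from 172 to 107 FPKM and Agpat2 from 26.9 to 16.5 FPKM (adjusted p = 0.0211, 0.0118 and 0.0211). Adipocyte markers, as a measured fact beside these lipid genes, had medians of 1.31, 0.99 and -0.20 above the control mean on the log2 scale in CM-RevDKO replicates 1, 2 and 3. Cd36 lost its call with any library left out (adjusted p of 0.0824 to 0.155), and Slc22a5, Gpam, Dgat2 and Agpat2 in 4, 3, 4 and 3 of the 6 such fits, at adjusted p up to 0.101. Scaled without the mitochondrially encoded genes, Cd36 also lost its call (adjusted p = 0.0559).

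Genes of glucose uptake and glycolysis went both ways, with 3 of 28 higher and 1 lower (4 and 2 adjusted over the list alone; median 0.10, camera adjusted p = 0.658). Pfkp, the platelet form of phosphofructokinase, rose from 15.7 ± 3.26 to 46.4 ± 4.21 FPKM (SD, n = 3, log2 1.52, adjusted p = 0.00412), and Pgk1, phosphoglycerate kinase, from 147 to 225 FPKM (adjusted p = 0.0171). Pfkfb1, which makes and removes the phosphofructokinase activator fructose 2,6-bisphosphate, fell from 7.19 ± 3.08 to 1.14 ± 0.738 FPKM (SD, n = 3, log2 -1.92, adjusted p = 0.0282). Fbp2, the muscle form of the gluconeogenic fructose bisphosphatase, fell from 26.8 ± 0.676 to 5.88 ± 1.22 FPKM (SD, n = 3, log2 -2.03, adjusted p = 7.54e-04). Pfkfb1 lost its call without control replicate 1 or 3 or CM-RevDKO replicate 2 or 3 (adjusted p up to 0.103), and Pgk1 without control replicate 1 or 2 or CM-RevDKO replicate 2 (adjusted p up to 0.0953).

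Camera called 2 lists of respiratory chain subunits and the ribosomal protein list higher in the libraries labelled CM-RevDKO, by small medians, and fry called none of these (adjusted p = 0.101 for complex I, 0.0708 for complexes II to V and 0.0790 for ribosomal proteins). Of 37 complex I subunits 34 had a positive log2 fold change, and the median was 0.19 (camera adjusted p = 5.22e-06; adjusted p = 0.717 with an estimated correlation). A single member passed the test: Ndufv3 rose from 465 to 840 FPKM (log2 0.85, adjusted p = 0.00465; 2 rose adjusted over the list alone). Of 40 subunits of complexes II to V none passed, with or without the list alone as the base (median 0.17, camera adjusted p = 7.30e-05; adjusted p = 0.571 with an estimated correlation), and the call ended with quantile normalization (median 0.07, adjusted p = 0.154; 1.22e-05 to 0.154 over the alternatives with the preset correlation). Cox7a1 stood at 2224 and 3284 FPKM (adjusted p = 0.0786) and Atp5g1 at 1290 and 1795 FPKM (adjusted p = 0.0982). Of 53 cytosolic ribosomal proteins 51 had a positive log2 fold change and 2 rose (3 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 2.48e-07; adjusted p = 0.571 with an estimated correlation). Rpl3 rose from 112 to 214 FPKM (adjusted p = 0.00780) and Rpl38 from 260 to 389 FPKM (adjusted p = 0.0424). With quantile normalization the medians of complex I and the ribosomal proteins were 0.09 and 0.12, with the calls held; scaled without the mitochondrially encoded genes, those of complex I and complexes II to V were 0.12 and 0.10. Of alternatives chosen after seeing the data, only CM-RevDKO replicate 3 against the controls gave medians of 0.11 for complex I and for the ribosomal proteins, from a single library. The ribosomal protein median was 0.15 without control replicate 2 and CM-RevDKO replicate 1 and 0.14 with the atrial covariate. As a measured fact beside them, CM-RevDKO replicates 1 and 2 stood apart from the other libraries in abundant transcripts that are not ordinary mRNAs. The feature mmu-mir-689-2 stood at 3683 and 1813 FPKM in them and at 25204 to 42294 FPKM in the rest, and mt-Atp8 at 18989 and 19303 FPKM against 8032 to 9769 FPKM; the ribosomal protein medians were 0.30 and 0.25 in these libraries and 0.11 in CM-RevDKO replicate 3. Rpl38 lost its call with any library left out (adjusted p of 0.0502 to 0.142) and under all 3 other scalings (adjusted p of 0.0576 to 0.0881), and Atp5g1 passed without CM-RevDKO replicate 3 (adjusted p = 0.0170).

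**Figure D2:**
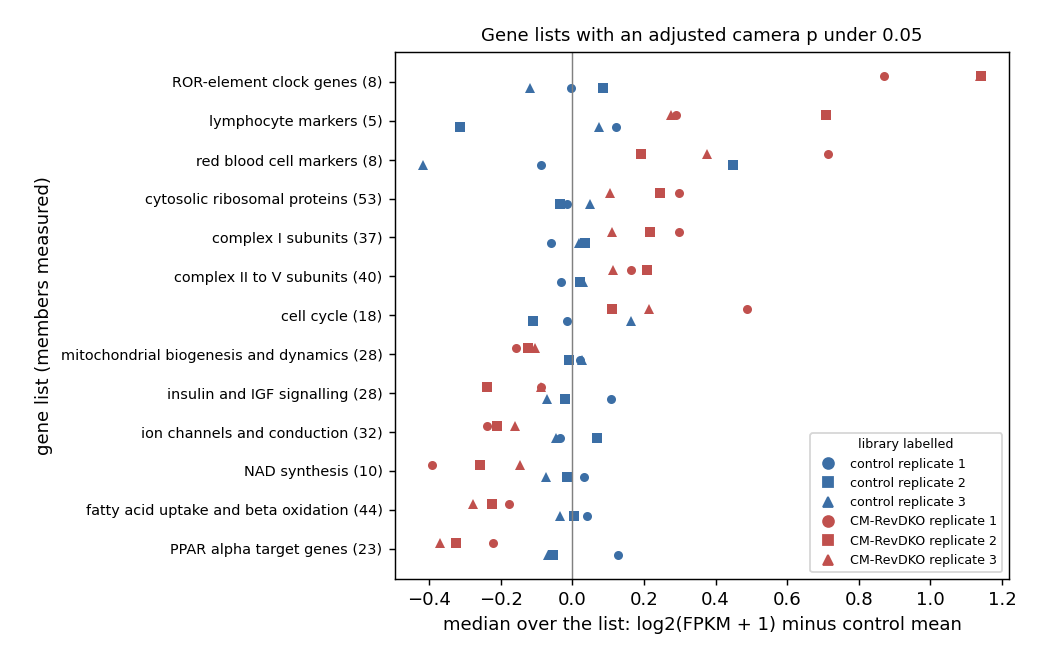
Median over each of the 13 called gene lists of the log2(FPKM + 1) value minus the mean of the libraries labelled control, for each library, with the number of measured members in parentheses. The ROR-element clock genes lie at 0.87 to 1.14 in the libraries labelled CM-RevDKO, and the fatty acid list at -0.28 to -0.18.

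The cardiac hormone genes rose strongly in the libraries labelled CM-RevDKO. Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, chromosome 4, 148000722 to 148002074), rose from 147 ± 15.6 to 677 ± 119 FPKM (SD, n = 3, log2 2.19, SE 0.14, adjusted p = 7.37e-04), and its neighbour Nppb, which encodes B-type natriuretic peptide (chromosome 4, 147985786 to 147987205), from 56.7 ± 17.4 to 385 ± 19.6 FPKM (SD, n = 3, log2 2.79, SE 0.21, adjusted p = 0.00115). Rcan1, a calcineurin inhibitor that calcineurin itself induces, rose from 17.4 to 37.5 FPKM (adjusted p = 0.00171). Of 23 fetal and stress genes of cardiomyocytes, 4 rose and none fell (5 and 2 adjusted over the list alone). The list was not called by camera (adjusted p = 0.709) but was by fry (adjusted p = 0.0353), and its median, -0.02, and mean, 0.19, differed in sign. The myosin heavy chains did not pass the test: Myh6 stood at 4421 ± 132 and 3496 ± 449 FPKM (SD, n = 3, adjusted p = 0.177) and Myh7 at 364 ± 136 and 239 ± 85.6 FPKM (SD, n = 3, adjusted p = 0.419). Myot, a Z-disc protein, fell from 8.72 ± 0.729 to 0.797 ± 0.0957 FPKM (SD, n = 3, log2 -2.43, adjusted p = 1.40e-04). Mylk4, a myosin light chain kinase, fell from 32.1 to 10.2 FPKM (adjusted p = 0.00465). Of 23 sarcomere and adult cardiomyocyte genes, however, 1 rose and 1 fell (6 and 2 adjusted over the list alone). That list was not called, and its median was positive (0.13, camera adjusted p = 0.401). As a measured fact beside Nppa and Nppb, atrial transcripts differed between libraries although the atria had been trimmed. Myl7, the atrial light chain, stood at 288 FPKM in CM-RevDKO replicate 1, 67.6 and 87.8 FPKM in replicates 2 and 3, and 27.8 to 51.9 FPKM in the libraries labelled control; Myl4 and Sln were likewise highest in CM-RevDKO replicate 1, at 227 and 146 FPKM. Among 12 measured atrial markers, 1 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 0.265).

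Ion channel and conduction genes were lower as a list (32 measured, 1 higher and 4 lower, 1 and 10 adjusted over the list alone; median -0.18, camera adjusted p = 0.00133). The adjusted p was 0.568 with an estimated correlation and 0.0353 by fry. Hcn2, a pacemaker channel, fell from 6.52 to 2.06 FPKM (log2 -1.30, adjusted p = 0.00295), and Kcnv2, a modifying subunit of voltage-gated potassium channels, from 2.14 to 0.306 FPKM (log2 -1.27, adjusted p = 0.00718). Kcne1, the beta subunit of the slow delayed rectifier, went the other way, from 6.96 ± 2.28 to 42.3 ± 4.50 FPKM (SD, n = 3, log2 2.48, adjusted p = 0.00130). Restricted to genes with a mean of at least 5 FPKM, the list lost its call (median -0.09, adjusted p = 0.183; 5.33e-04 to 0.183 over the alternatives with the preset correlation).

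On the log2(FPKM + 1) scale, the largest changes outside these groups included rises of genes at low levels in the libraries labelled control. Ppp1r1b, which encodes the phosphatase inhibitor DARPP-32, rose from 1.01 ± 0.407 to 38.8 ± 18.9 FPKM (SD, n = 3, log2 4.23, adjusted p = 9.79e-04). Slc41a3, a member of a magnesium transporter family, rose from 7.13 ± 1.04 to 115 ± 4.15 FPKM (SD, n = 3, log2 3.84, adjusted p = 1.72e-05). Cdkn1a, the cell cycle inhibitor p21, rose from 4.88 ± 0.748 to 79.4 ± 6.93 FPKM (SD, n = 3, log2 3.78, adjusted p = 1.72e-05). Fhit rose from 0.935 to 8.04 FPKM (adjusted p = 0.00346). Among the falls, Ces1d, a carboxylesterase, went from 65.0 ± 3.30 to 10.1 ± 1.09 FPKM (SD, n = 3, log2 -2.58, adjusted p = 6.30e-05) and Rhobtb1 from 62.0 to 21.1 FPKM (adjusted p = 7.37e-04). Fah, the last enzyme of tyrosine breakdown, fell from 9.35 ± 3.92 to 2.36 ± 0.686 FPKM (SD, n = 3, adjusted p = 0.0301). Liver transcripts were present in control replicate 2, where Alb, serum albumin, stood at 100.3 FPKM and Fah was highest, at 13.7 FPKM. Alb stood at 3.84 and 1.88 FPKM in control replicates 1 and 3, at 10.9 and 11.6 FPKM in CM-RevDKO replicates 1 and 2, and was listed at 0 in CM-RevDKO replicate 3. Fah lost its call without control replicate 3 or CM-RevDKO replicate 2 or 3 (adjusted p up to 0.105).

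**Figure D3:**
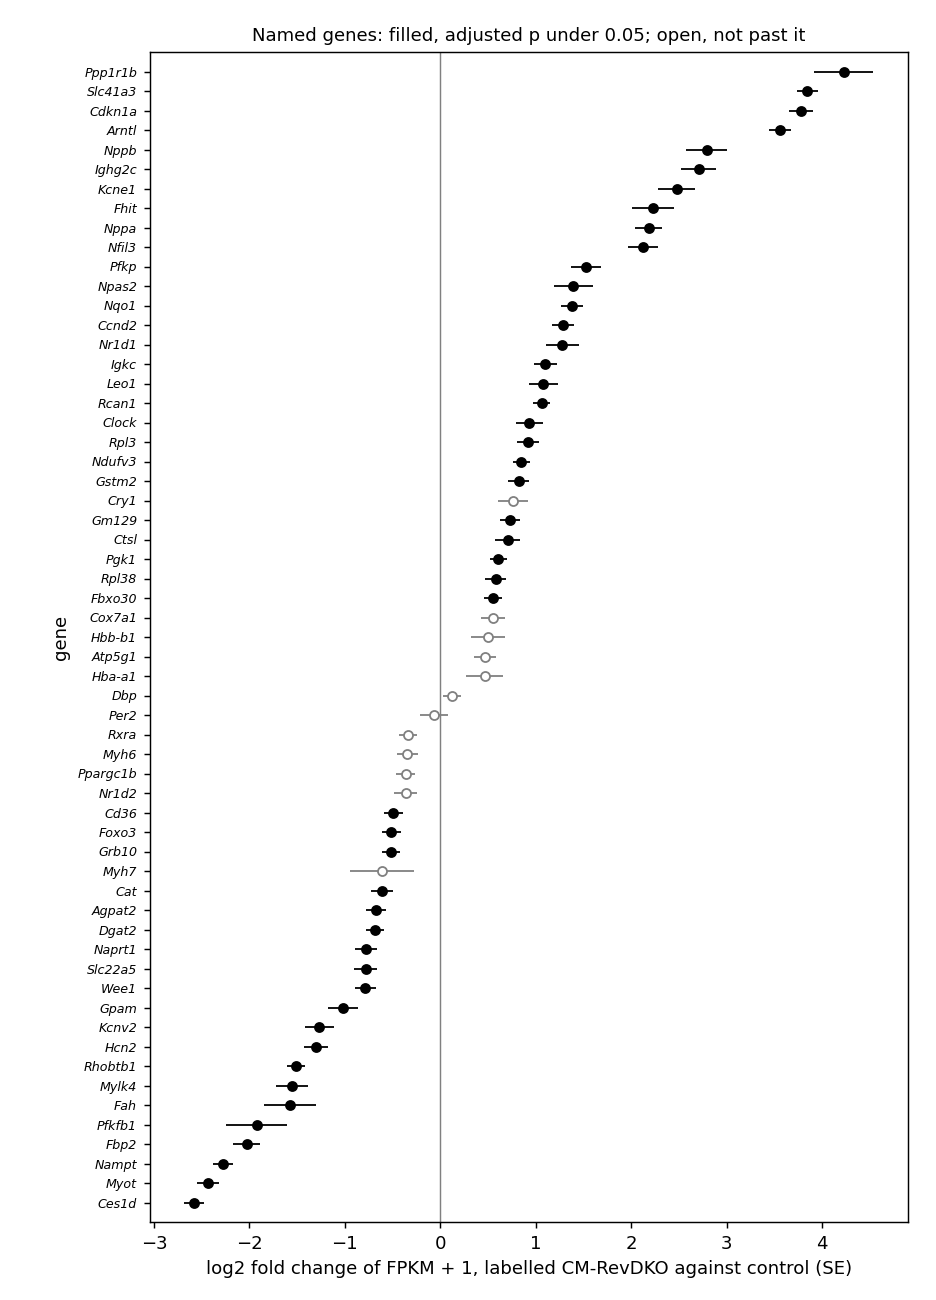
Log2 fold change of FPKM + 1 between the libraries labelled CM-RevDKO and those labelled control for the named genes reported here, with SE as bars; filled points passed the test and open points did not. They range from -2.58 for Ces1d to 4.23 for Ppp1r1b.

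Smaller list changes followed in growth and regulatory genes. In the cell cycle list Cdkn1a and Ccnd2, a D-type cyclin (16.6 to 42.0 FPKM, adjusted p = 0.00218), rose and Wee1 fell, of 18 measured, with the same counts adjusted over the list alone. Cdkn1a and Wee1 hold the cycle back and Ccnd2 drives it. The list's median was 0.14 (camera adjusted p = 0.0423; adjusted p = 0.911 with an estimated correlation; fry adjusted p = 0.0790), and the call was lost without control replicate 1 or 2 or CM-RevDKO replicate 1 or 3 (adjusted p = 0.112, 0.191, 0.158 and 0.0543). That median was 0.23 without control replicate 3, 0.29 and 0.22 without CM-RevDKO replicate 2 or 3, and 0.093 scaled without the mitochondrially encoded genes; of alternatives chosen after seeing the data, the atrial covariate gave 0.016 and leaving out control replicate 2 and CM-RevDKO replicate 1 gave 0.062, both without a call. Of 28 insulin and IGF signalling genes 2 fell (2 higher and 5 lower adjusted over the list alone): Grb10, an adaptor that restrains the insulin receptor, from 16.7 to 11.4 FPKM (adjusted p = 0.0379), and the transcription factor Foxo3 from 16.8 to 11.5 FPKM (adjusted p = 0.0485). The median was -0.16 (camera adjusted p = 0.0167; adjusted p = 0.717 with an estimated correlation; fry adjusted p = 0.194). It was -0.099 without CM-RevDKO replicate 2 and -0.088 with only CM-RevDKO replicate 3 against the controls, an alternative chosen after seeing the data. The call was lost without control replicate 1 (adjusted p = 0.127). Mitochondrial biogenesis and dynamics had no member past the test among 28, by either adjustment (median -0.09, camera adjusted p = 0.0250; adjusted p = 0.571 with an estimated correlation; fry adjusted p = 0.0833). Ppargc1b stood at 9.11 and 6.86 FPKM (adjusted p = 0.128) and Rxra at 14.4 and 11.1 FPKM (adjusted p = 0.128). That list's call was lost without control replicate 3 (adjusted p = 0.109) or CM-RevDKO replicate 1 (adjusted p = 0.142), and its median was -0.14 without control replicate 2 and -0.15 scaled without the mitochondrially encoded genes.

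Of 31 NRF2 and antioxidant genes, 2 rose and 1 fell (3 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.812). Nqo1, a quinone reductase, rose from 33.4 to 88.0 FPKM (log2 1.38, adjusted p = 0.00187), Gstm2, a glutathione transferase, rose from 52.2 to 92.6 FPKM (adjusted p = 0.0106), and Cat, catalase, fell from 73.9 to 48.0 FPKM (adjusted p = 0.0471). Of 27 autophagy and proteasome targets of FOXO, Ctsl, a lysosomal protease (66.8 to 109 FPKM, adjusted p = 0.0365), and Fbxo30, a ubiquitin ligase subunit (4.05 to 6.40 FPKM, adjusted p = 0.0306), rose and Foxo3 fell (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.683). Grb10, Foxo3, Cat, Ctsl and Fbxo30 lost their calls with any library left out (adjusted p of 0.0599 to 0.159), and Gstm2 without control replicate 1 (adjusted p = 0.0537). Foxo3 also lost it with median-of-ratios scaling (adjusted p = 0.0583) and quantile normalization (adjusted p = 0.0506), and Fbxo30 with scaling without the mitochondrially encoded genes (adjusted p = 0.0515).

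Among cell type markers, lymphocyte and red blood cell lists were called. Igkc, the kappa light chain of antibodies, rose from 8.78 to 19.9 FPKM (adjusted p = 0.00472), as the single call of 5 measured lymphocyte markers by either adjustment (median 0.51, camera adjusted p = 0.0167; adjusted p = 0.571 with an estimated correlation; fry adjusted p = 0.0790). Ighg2c, an antibody heavy chain constant region, was among the largest rises on the log2(FPKM + 1) scale, from 0.581 ± 0.333 to 9.17 ± 0.883 FPKM (SD, n = 3, log2 2.71, adjusted p = 7.54e-04), while the B cell receptor component Cd79a, chosen after its values were seen, stood at 1.44 and 1.61 FPKM (adjusted p = 0.839). The 8 red blood cell markers all had a positive log2 fold change and none passed by either adjustment (median 0.41, camera adjusted p = 0.0420; adjusted p = 0.918 with an estimated correlation; fry adjusted p = 0.447). Hbb-b1 stood at 1466 and 2037 FPKM (adjusted p = 0.214) and Hba-a1 at 2452 and 3300 FPKM (adjusted p = 0.298). The lymphocyte call was lost without control replicate 2 (adjusted p = 0.0783) or CM-RevDKO replicate 2 (median 0.33, adjusted p = 0.0799), and the red blood cell call without control replicate 1 or 3 or CM-RevDKO replicate 1 or 3 (adjusted p = 0.162, 0.216, 0.128 and 0.0753). The lymphocyte list was fixed with 19 members, and its median was 0.84 with a pseudocount of 0.1. The median was 0.92 over only those members with a mean of at least 5 FPKM. Of alternatives chosen after seeing the data, it was 0.21 without control replicate 2 and CM-RevDKO replicate 1, 0.32 with the atrial covariate and 0.28 with only CM-RevDKO replicate 3 against the controls. The red blood cell median was 0.69 without control replicate 2 and 0.24 without control replicate 3. Across all 53 lists, 13 were called, 7 higher and 6 lower. With an estimated correlation camera called 0 lists (3 had an unadjusted p under 0.05), and fry called 4.

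**Figure D4:**
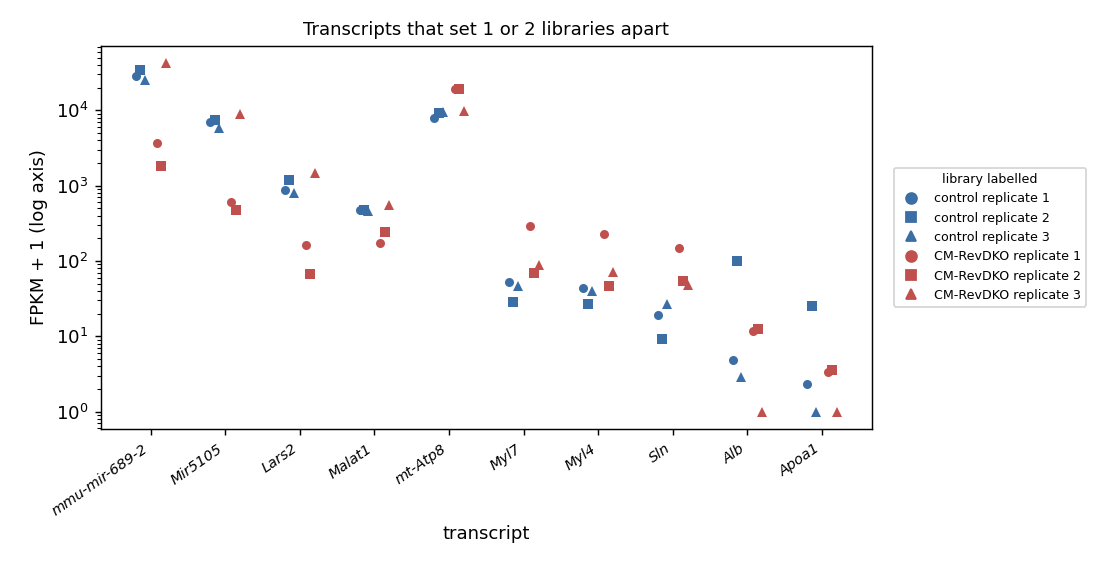
FPKM + 1 on a log axis, per library, of transcripts that set libraries apart. CM-RevDKO replicates 1 and 2 have low mmu-mir-689-2, Mir5105, Lars2 and Malat1 and high mt-Atp8, CM-RevDKO replicate 1 has the highest Myl7, Myl4 and Sln, and control replicate 2 has the highest Alb and Apoa1.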

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

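The alternatives with only CM-RevDKO replicate 3 against the controls, without control replicate 2 and CM-RevDKO replicate 1, and with the mean of Myl7 and Myl4 as an atrial covariate were tests chosen after the result was seen; the other 17 alternatives were planned. With only the third CM-RevDKO library, the spread comes from the controls and that library is assumed to vary like them, so neither a kept nor a lost call there bears on the group. The cause of a change was not tested, except that leaving out libraries, adding a block or a covariate, and testing against a fold of 1.5 take power by construction. The 332 changed genes became 120 to 322 with each library left out, 35 against a fold change of 1.5, 21 with only the third CM-RevDKO library (16 shared with the 332), 105 without the 2 libraries with signs of other tissue (90 shared) and 39 with the atrial covariate (38 shared); pseudocount, filters, the 3 scalings and array weights gave 312 to 451. With the replicate number as a block 115 genes were called (109 shared) and 12 lists; libraries of the same number did not deviate together (r = -0.04, -0.06 and 0.09 across genes, and 1 of the 3 numbers gave the best match to itself), so the number is not known to pair them. The 13 called lists became 11 to 13 with each library left out, 0 with an estimated correlation and 4 with fry (3 shared). Nr1d1 kept its direction throughout (1.08 to 1.40 with each library left out, adjusted p at most 0.0483) and lost its call against a fold of 1.5 (1.28), with only the third CM-RevDKO library (1.21), without the 2 libraries (1.29) and with the atrial covariate (1.17); over all alternatives its adjusted p was 0.00898 to 0.407. Nr1d2 stayed negative and short of the threshold throughout. Reversals came from 3 genes not past the test: Per2 (-0.15 to 0.089 with each library left out, reversed without control replicate 1), Dbp (-0.023 with the atrial covariate) and Myh7 (0.21 with the atrial covariate). Of the 48 named genes past the test, 26 kept the call in all 6 leave-outs and 8 lost it in each. The call was lost by 32 against a fold of 1.5 and by 18 with the replicate number as a block. It was lost by 20 without the 2 libraries with signs of other tissue and by 28 with the atrial covariate. No called list changed direction under any alternative. With the preset correlation and beyond leaving out 1 library, the cell cycle call ended in 5 alternatives with at least 2 libraries per group, the red blood cell call in 3, that of mitochondrial biogenesis in 2, that of complexes II to V with quantile normalization and that of ion channels with a mean of at least 5. Depth is unknown, so its limit on low genes cannot be given.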

Other observations

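The tests on Nr1d1, those on left-over atrial tissue and the test on neighbouring genes that leaves out overlaps were chosen after the result was seen. The genes named in this paragraph and the next were chosen after their values were seen. Rpl3l, the striated muscle paralog of the ribosomal protein gene Rpl3, fell from 141 to 57.3 FPKM in the libraries labelled CM-RevDKO (log2 -1.28, adjusted p = 7.54e-04), while Rpl3 itself rose. Hopx, a homeodomain regulator of cardiac genes, fell from 206 to 96.6 FPKM (log2 -1.09, adjusted p = 0.00218). Idh1 and Idh2, isocitrate dehydrogenases, fell from 23.5 to 14.0 FPKM (adjusted p = 0.0113) and from 689 to 463 FPKM (adjusted p = 0.0464). They were the members that changed of 24 genes in the TCA cycle list, which also holds the cytosolic Idh1 (camera adjusted p = 0.846). Bckdhb and Dbt, subunits of the branched-chain ketoacid dehydrogenase, fell from 33.0 to 23.3 FPKM (adjusted p = 0.0333) and from 22.1 to 14.0 FPKM (adjusted p = 0.0364), of 23 genes of branched-chain amino acid breakdown (camera adjusted p = 0.224). Ppp1r3a, a glycogen-targeting phosphatase subunit, fell from 30.4 to 14.2 FPKM (adjusted p = 0.00998). The kappa variable segment Igkv1-117 was listed at 0, 0 and 0.189 FPKM in the libraries labelled control and at 1.55, 2.26 and 1.95 FPKM in those labelled CM-RevDKO (adjusted p = 0.00828).

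The remaining lists were not called. Extracellular matrix and fibrosis genes had none of 44 past the test (median 0.09 on the log2 scale), and neither did 18 fibroblast markers (camera adjusted p = 0.848), 22 macrophage and monocyte markers (camera adjusted p = 0.455) or 28 interferon response genes (camera adjusted p = 0.455). The macrophage and matrix medians were 0.57 and 0.49 above the control mean in CM-RevDKO replicate 1 and between -0.16 and -0.03 in replicates 2 and 3. Among 28 calcium handling genes, 1 fell (Cacnb2, adjusted p = 0.0267; camera adjusted p = 0.805). Bmp10, an atrial gene, was listed at 1.94 FPKM in CM-RevDKO replicate 1 and at 0 in the other 5 libraries.

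Nr1d1 was higher in the libraries labelled CM-RevDKO (log2 1.28). Wrong labels, of a single library or of both groups, were argued against by the mean of the other 7 clock genes with ROR elements, where REV-ERB competes with the ROR activators. In their mean log2 value the lowest library labelled CM-RevDKO lay 0.76 above the highest labelled control, with a within-group SD of at most 0.18. Not every member rose: 2 of the list had a negative log2 fold change, and 1 of these fell past the test. Reads of the overlapping Thra stay open, since its own log2 fold change of -0.46 (SE 0.10, adjusted p = 0.0723) does not exclude reads that were assigned to Nr1d1 in place of Thra. A further candidate explanation that stays open is lost repression of a transcript that the deletion leaves detectable, since REV-ERB acts on its own gene: the other 7 genes had a median log2 fold change of 0.93, with 5 above 0. Exon-level reads with strand, not analysed here, would test both.

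Nppa and Nppb were higher in the libraries labelled CM-RevDKO, and the atrial transcripts Sln, Myl7 and Myl4 were highest in CM-RevDKO replicate 1. With the mean log2 value of Myl7 and Myl4 as a covariate, the log2 fold change of Nppa was 1.86 (SE 0.12, 2.19 without it, adjusted p = 0.00456) and that of Nppb 2.62 (SE 0.31, 2.79 without it, adjusted p = 0.0335), which argues against left-over atrial tissue as the whole source of either. Whether left-over atrium may account for Sln, Myl7 and Myl4 in CM-RevDKO replicate 1 was not decided: over the other 8 atrial markers the median difference from replicates 2 and 3 was 0.18 on the log2 scale, with 4 above 0, at percentile 89.1 of 10000 lists matched on expression. Bmp10, an atrial gene under the filter on low values and so not among the 8, was listed at 1.94 FPKM in CM-RevDKO replicate 1. It was listed at 0 in every other library. A change of Sln, Myl7 and Myl4 within ventricular cardiomyocytes of the libraries labelled CM-RevDKO stays open for the group and was not tested. If shared by those libraries, it would not by itself set replicate 1 above replicates 2 and 3.

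Ribosomal protein and complex I to V subunit genes had a median log2 fold change of 0.19 over 130 genes, of which 3 passed the test. Camera called the lists of complex I, complexes II to V and ribosomal proteins with its preset correlation, but they had adjusted p = 0.717, 0.571 and 0.571 with an estimated correlation and 0.101, 0.0708 and 0.0790 by fry. All 3 technical explanations tested stay open. A gain of short transcripts as a class may contribute, since 130 genes of other families with short mRNAs had a median of 0.17 (bootstrap SE 0.02). That SE comes from resampling genes and leaves out the spread between libraries. These families were picked by symbol (Mrpl, Mrps, Psma, Psmb, Lsm, Snrp and Timm), and transcript length was not used. A shift that they share for another reason is therefore not told apart from one by length. The library structure of CM-RevDKO replicates 1 and 2 may contribute, since the median shift was 0.11 in replicate 3 and 0.25 in replicates 1 and 2, and so may the scaling, since quantile normalization lowered the median to 0.084 from 0.19. A biological change in the libraries labelled CM-RevDKO is open beside them.

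The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 332 changed genes and the highest of the others 3, so 1 split, the real one, reached the count. For gene lists, the real split gave 13 calls and the highest of the others 21, with 3 splits reaching 13; that split joins control replicates 1 and 2 with CM-RevDKO replicate 1.

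Changed genes lay side by side more often than in random draws, as the hypothesis that neighbouring genes change together predicts. Among 12801 genes with a position, 15 neighbouring pairs changed the same way against a mean of 4.22 in 10000 draws (one-sided permutation p = 0.0001, the smallest they can give). The draws above were not matched on expression. Overlapping genes can share reads, and close genes without an annotated overlap stayed in below, so shared reads are not excluded. With overlapping genes left out, 11 pairs remained against a mean of 3.81 (one-sided permutation p = 9e-04). They include Nppb and Nppa, Kcne1 and Rcan1 on chromosome 16 (92346001 to 92359468 and 92391951 to 92466169, both higher) and Tmem82 and Slc25a34 on chromosome 4 (141614233 to 141618633 and 141618819 to 141623891, both lower), named after their values were seen. The hypothesis that the region around Nr1d1 changed as a whole was not borne out: Ppp1r1b, which rose, ends 410136 bp from Nr1d1, but of 32 other tested genes within 1 Mb 0 passed the test (one-sided Fisher's exact p = 1).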
